A study of Mus musculus with 60 samples.

How the data were processed

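Gene expression was measured by RNA sequencing in the prefrontal cortex of 60 mice of the C57BL/6J strain. The labels name 12 groups of 5 libraries, made of 2 genotypes, 3 treatments and both sexes. The genotypes were wild type (WT) and heterozygous for the N2373K allele of Chd8 (Het), a gene for a chromatin remodeling protein whose loss-of-function variants are linked to autism. Treatment was fluoxetine, a selective serotonin reuptake inhibitor, lithium, a mood stabilizer, or vehicle. Per the labels' protocols the drugs reached the pups through the milk of their mothers from postnatal day 3 to 24, for 3 weeks, and the tissue was taken on postnatal day 25. Libraries were made with a stranded kit that selects polyadenylated RNA, per the labels. Litters are not given in the sources used here, so pups of one group, or of different groups given the same treatment, can share a mother. P-values measure only the spread between these samples.

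The submitters' processing notes name Salmon 0.11.2, DESeq2 1.19.11, R 3.6.0 and the mouse genome build GRCm38, without saying which step used which or which gene annotation was taken. The deposited table held 18088 genes in 60 columns of a normalized signal, a value that is never negative and need not be whole. Each deposited column stepped in whole multiples of its smallest value above 0. Dividing by that step returned whole numbers for 100% of the values at a tolerance of 0.001, so the deposited signal was whole reads divided by 1 size factor per library, with size factors from 0.818 to 1.0723 relative to each other. The recovered reads ran from 24.05 to 31.65 M (mega-reads) per library, with a median of 28.32 M. The most abundant gene took 2.27% to 3.55% of a library's reads and the 10 most abundant took 7.12% to 10.94%. Gene symbols, biotypes and coordinates came from GENCODE M21 on GRCm38, which named 18077 of the genes, and 3 genes were at 0 in every library. All columns were used.

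The deposited values were kept as normalized and taken to log2(value + 1). Fold changes are on that scale, which understates the change of low genes. Genes with a value of at least 10 in at least 5 libraries were tested, which left 17807. The design had fixed an edgeR test for raw counts and limma for normalized values, and as the values were normalized the limma route was the one used. In R 4.3.3, limma 3.58.1 fitted 1 mean per group over all 60 libraries with an intensity trend (limma-trend, 48 residual degrees of freedom), and every comparison was a contrast of those means. All tests were two-sided. A gene was called where its Benjamini-Hochberg adjusted p was under 0.05 within its comparison. The 10 main comparisons were Het against WT under vehicle, and each drug against vehicle in each genotype, in each sex. Beside them stood Het against WT under each drug, averages over both sexes, the interactions of genotype, drug and sex, and male against female WT vehicle mice. Replicates were compared in 120 pairs within groups, and their chi-square per degree of freedom ran from 4.12 to 69.97, so no pair lay within sampling noise.

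Gene lists for the drugs' targets, for pathways and for the cell types and neighboring regions that the dissected tissue could hold were written down from general knowledge. There were 31 lists, each tested in the 10 main comparisons with camera, which compares a list with all other genes. The main setting was a preset correlation between genes of 0.01, and the same test with an estimated correlation and the fry test were alternatives. Adjustment was over all lists and comparisons. A list's score in a library was the mean of its genes' log2 values, each centered over the 60 libraries. The correlation of fold changes between comparisons was taken across the 17807 genes, which are not independent replicates. Where 2 comparisons shared vehicle libraries, 200 simulations of unchanged groups gave the value that sharing alone produces, and the vehicle libraries were also split between the comparisons.

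The samples, groups, gene lists, tests, thresholds and the rule for naming genes were fixed before the data were examined. Named genes were Chd8 in every group. For each comparison they were up to 12 higher and 12 lower called genes with the largest change and up to 6 with the smallest adjusted p, among genes with a proper symbol and a mean of at least 50. Further named genes were up to 4 members of each list with the smallest p, up to 8 per interaction, and up to 8 called in the most comparisons. The sex-linked genes Xist, Ddx3y, Kdm5d, Eif2s3y and Uty were also named, as were Slc6a4, Htr1a, Htr2a, Htr2c, Gsk3b, Axin2, Impa1, Inpp1 and Bdnf, and up to 4 markers of other tissues. Only some of these are printed, as examples, and a result on 1 gene is not reported here. Genes with near-identical copies are given as uncertain, since it is not given how reads were divided between copies.

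The alternatives fixed with the design were quantile normalization, rescaling to the same total, no filter or a minimum of 50, a pseudocount of 0.5 or 5, array weights per library, a fit of only the groups compared, the replicate number as a block, 2 tissue scores (striatal and leptomeningeal) as covariates, and leaving out each library in turn. Chosen after seeing the data were the edgeR 4.0.16 quasi-likelihood test, the DESeq2 1.42.0 Wald test and limma-voom on the recovered reads, 4 tissue scores (olfactory bulb, myelin, striatal and leptomeningeal) as covariates, a fit without the 16 libraries whose olfactory bulb score was above 1, and Het fluoxetine against WT vehicle mice. Each comparison was also set among 100 splits of its libraries, the real one included. The procedure was tested on simulated reads with known changes. For fluoxetine in WT males, with 17730 genes, 24 of 50 genes changed 1.25-fold were called and 43 of 50 changed 1.5-fold. Called too were 48 of 50 changed 2-fold and 48 of 50 changed 3-fold, with 9 unchanged genes among 172 calls. For lithium in Het females, with 17725 genes, 26, 43, 47 and 50 of 50 were called at those folds, with 12 unchanged genes among 178 calls. The simulated genes varied independently of each other, without shared tissue or litter differences, so these rates need not hold for the real libraries.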

Results

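RNA of the prefrontal cortex was sequenced from 60 mice on postnatal day 25, with 5 libraries in each of 12 groups. Reads per library ran from 24.05 to 31.65 M, with a median of 28.32 M. Among WT mice the range was 25.98 to 29.28 M in vehicle males, 25.47 to 30.69 M in vehicle females, 26.01 to 31.65 M in fluoxetine males, 25.38 to 30.85 M in fluoxetine females, 25.39 to 29.64 M in lithium males and 26.27 to 31.21 M in lithium females. Among Het mice it was 25.31 to 29.62 M, 27.91 to 30.57 M, 25.98 to 29.06 M, 24.05 to 30.44 M, 26.25 to 29.82 M and 25.65 to 30.88 M in the same order. Levels of Xist, the RNA that silences an X chromosome, were 0 to 50.58 normalized counts in the 30 males and 16474 to 31520 in the 30 females. The Y-linked gene Ddx3y stood at 1278 to 2481 in the males and at 0 to 39.22 in the females, so these genes matched the labelled sex in all 60 libraries. Each fold change compares 5 libraries with 5 and is given on the log2 scale with its standard error. A library counts as showing a change when it lies on that side of the mean of the group it is compared with.

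Chd8 mRNA was lower in Het than in WT mice under every treatment. Chd8 (chromosome 14, 52198151 to 52257780 on GRCm38), a chromatin remodeling gene of the CHD family, stood at 2671 ± 134 normalized counts (SD, n = 30) in Het and 3094 ± 91.7 (SD, n = 30) in WT mice. WT group means were 3089 ± 57.0 and 3120 ± 117 (SD, n = 5) in vehicle males and females, 3097 ± 44.0 and 3071 ± 162 with fluoxetine, and 3068 ± 77.9 and 3118 ± 81.7 with lithium. Het group means were 2675 ± 134 and 2634 ± 77.2 (SD, n = 5) in vehicle males and females, 2735 ± 228 and 2657 ± 152 with fluoxetine, and 2690 ± 125 and 2634 ± 84.2 with lithium. The Het minus WT difference under vehicle was −0.21 ± 0.04 in males (limma, adjusted p = 0.0450) and −0.24 ± 0.04 in females (adjusted p = 0.00558), lower in 5 of 5 Het libraries each. Neither drug changed Chd8 in either genotype, with log2 fold changes between −0.02 and 0.03 and adjusted p from 0.649 to 0.998. The library labelled Het fluoxetine male replicate 5 stood at 3072, above the lowest WT library at 2951.

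**Figure D1:**
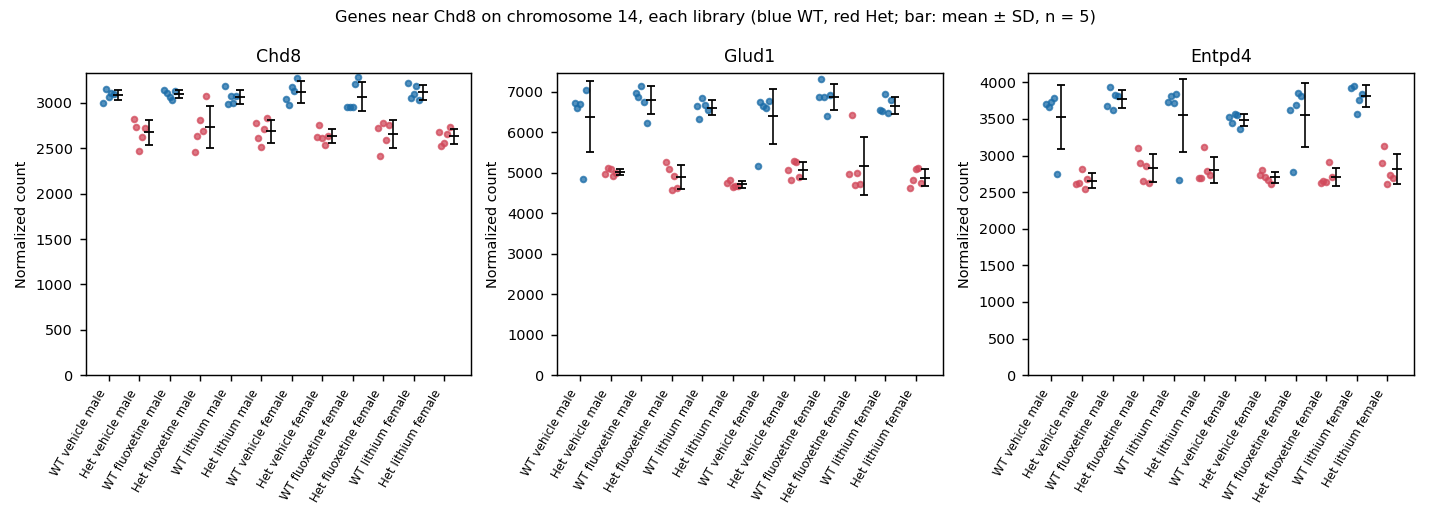
Normalized counts of Chd8, Glud1 and Entpd4 (vertical axes, from 0) in each library of the 12 groups (horizontal axes), with WT in blue, Het in red, and the group mean ± SD of 5 libraries as a bar. Het groups had Chd8 means between 2634 and 2735 and WT groups between 3068 and 3120.

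The first question was what differed between the genotypes without a drug. In vehicle males Entpd4, an enzyme that breaks down nucleotides in intracellular membranes, differed by −0.40 ± 0.07 (adjusted p = 0.0268). Glud1, the mitochondrial glutamate dehydrogenase, differed by −0.33 ± 0.07 (adjusted p = 0.0450), from 6379 ± 876 to 5016 ± 81.2 counts (SD, n = 5). In vehicle females Entpd4 differed by −0.37 ± 0.07 and Glud1 by −0.33 ± 0.07, and Pam16, a part of the mitochondrial protein import motor, was higher by 1.10 ± 0.22 (adjusted p = 0.0432 for each). The WT vehicle females were low in Pam16 (75.9 ± 7.85 counts, SD, n = 5), and it was also called higher with fluoxetine (0.86 ± 0.22) and lithium (1.13 ± 0.22) against that same group. Each of these differences was shown by 5 of 5 Het libraries. Glud1 and Entpd4 lie on chromosome 14 like Chd8, at 34310727 to 34345265 and at 69337174 to 69367270. Entpd4 has a near-identical neighbor, Entpd4b, so its level is uncertain. As an average over both sexes Chd8 (−0.23 ± 0.03, adjusted p = 6.67e-06), Entpd4 (−0.38 ± 0.05), Glud1 (−0.33 ± 0.05), the deubiquitinase gene Usp11 (−0.19 ± 0.03) and the peroxisomal gene Phyh (−0.16 ± 0.03) were lower in Het mice, and Csad, an enzyme of taurine synthesis, was higher (0.24 ± 0.05, adjusted p = 0.00628).

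The counts were 3 called genes in vehicle males (0 higher, 3 lower; 1463 at an unadjusted p under 0.05) and 4 in vehicle females (1 higher, 3 lower; 1149 unadjusted). The sex average had 10 (4 higher, 6 lower), with 1 higher and 5 lower under quantile normalization and 9 higher and 6 lower after rescaling. In females quantile normalization gave 0 higher and 1 lower and rescaling 0 higher and 2 lower. Without Het vehicle male replicate 1 no gene was called in males, and without Het vehicle female replicate 4 none in females. In a fit of only the groups compared, 0 genes were called in males. Chd8, Glud1 and Entpd4 in males and Glud1, Entpd4 and Pam16 in females kept their direction and lost their calls without the 16 libraries with the highest olfactory bulb scores.

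Of the 31 gene lists, 11 moved in vehicle males and 4 in vehicle females with the preset correlation. In males glucocorticoid-responsive genes were lower, with a median of −0.29 over 17 genes (adjusted p = 4.01e-08, and adjusted p = 0.724 with an estimated correlation). No member was called over all genes, and 4 were lower adjusted over the list alone. Presynaptic release genes (median −0.10, adjusted p = 9.91e-06) and circadian clock genes (−0.15, adjusted p = 0.000493) were lower too, both with an adjusted p = 0.774 with an estimated correlation. Smaller male differences were lower postsynaptic density (−0.05) and inhibitory synapse genes (−0.07, adjusted p = 0.0114 and 0.0126). Higher were heat shock genes (0.10), cholesterol synthesis genes (0.06) and cytosolic ribosomal proteins (0.05, adjusted p = 0.00389, 0.0285 and 0.000280). The ribosomal list turned direction without Het vehicle male replicate 3 (adjusted p = 0.888). Markers of neighboring tissue moved beside them in these males, with choroid plexus markers at −0.60 (adjusted p = 0.0157), striatal markers at −0.35 (adjusted p = 0.0227) and olfactory bulb markers at 0.83 (adjusted p = 0.0391). In females oligodendrocyte and myelin markers were lower, with a median of −0.78 over 24 genes (adjusted p = 3.03e-16, and adjusted p = 0.724 with an estimated correlation). None of them was called over all genes, and 12 were lower adjusted over the list alone. Leptomeningeal and endothelial markers were higher in females (0.26 and 0.05, adjusted p = 0.000442 and 0.0285), the latter turning direction with 2 tissue scores. Autism risk genes had a median of −0.04 over 66 genes (adjusted p = 4.54e-05), and the 1 member called was Chd8 itself. Lists with no such p given had an adjusted p = 0.949 with an estimated correlation.

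Under fluoxetine, 211 genes were called between Het and WT males (96 higher, 115 lower), against 1 in a fit of only the groups compared. Glud1 differed by −0.47 ± 0.07 (adjusted p = 7.43e-05), Entpd4 by −0.42 ± 0.07 and Tnfrsf25, a death receptor of lymphocytes, by −1.16 ± 0.21 (adjusted p = 0.00150). The zinc transporter gene Slc39a2 differed by −0.75 ± 0.13, the microglial gene Aif1 by −0.77 ± 0.18 and Xlr3b by −2.60 ± 0.61. Proteasome genes Psma6 (0.33 ± 0.07) and Psmd1 (0.23 ± 0.04) and the complex I gene Ndufv2 (0.31 ± 0.07) were higher. Each was shown by 5 of 5 Het libraries. With quantile normalization 65 were higher and 122 lower, after rescaling 36 and 154, and without WT fluoxetine male replicate 1 the count was 52. In females 7 genes were lower and none higher, among them Glud1 (−0.42 ± 0.07, adjusted p = 0.00124), the maternally expressed noncoding RNA Rian (−0.28 ± 0.05) and Fli1, a transcription factor of blood and endothelial cells (−0.53 ± 0.11). Quantile normalization gave 2 higher and 10 lower genes there, and 2 were called without WT fluoxetine female replicate 5. Under lithium only Glud1 was called in males (−0.49 ± 0.07, adjusted p = 3.29e-05), and Glud1 (−0.45 ± 0.07), Entpd4 (−0.44 ± 0.07) and Chd8 (−0.24 ± 0.04) in females. Chd8 stood at −0.19 ± 0.04 in lithium males, which missed the threshold (adjusted p = 0.245) although lower in 5 of 5 Het libraries.

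The next question was what 3 weeks of fluoxetine did in each genotype and sex, and immediate early genes were lower in all 4 groups. Arc, an immediate early gene whose protein acts at synapses, fell by 1.68 on the log2 scale in WT males (SE 0.23, adjusted p = 7.45e-06) and by 1.63 in WT females (adjusted p = 1.36e-05). It fell by 2.13 in Het males (adjusted p = 1.36e-08) and by 1.85 in Het females (adjusted p = 8.72e-07), each time in 5 of 5 libraries. In WT males that was from 5058 ± 886 to 1586 ± 332 normalized counts (SD, n = 5), and in Het males from 4712 ± 813 to 1075 ± 161. The transcription factor Egr2 changed by −1.65, −1.74, −1.47 and −1.60 in WT males, WT females, Het males and Het females, Fos by −1.19, −1.45, −1.24 and −1.12, and Klf10 by −1.16, −0.95, −1.01 and −1.13 (adjusted p between 4.79e-09 and 0.000311). Junb and Nr4a1, both activity-induced transcription factors, fell in all 4 comparisons, with changes of −0.71 to −0.96 and −0.69 to −0.90. Averaged over both sexes, Arc changed by −68.3% in WT and −74.8% in Het mice, and Fos by −60% and −55.8%.

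Of 28 measured immediate early genes 13 were lower in WT males, 14 in WT females, 14 in Het males and 14 in Het females, and 1 was higher, in Het females. Adjusted over the list alone, 17, 19, 17 and 15 were lower and 2 higher in Het females. The list medians were −0.47, −0.51, −0.56 and −0.48 (adjusted p = 8.95e-26, 1.42e-22, 2.98e-09 and 2.88e-08). With an estimated correlation the adjusted p was 0.115, 0.124, 0.724 and 0.724, and the fry test, which asks whether a list's genes move one way on balance, gave an adjusted p of 0.000532, 0.000323, 0.000986 and 0.00489. Per1, a clock gene that neuronal activity also induces, changed by −0.62, −0.61, −0.42 and −0.56, in 5 of 5 libraries except 4 of 5 in Het males. Among the fluoxetine comparisons the circadian list as a whole was called in WT males (median −0.06, adjusted p = 0.0267, and adjusted p = 0.949 with an estimated correlation), where Nr1d1 (−0.38 ± 0.10) and Bhlhe40 (−0.54 ± 0.13) were also lower. Tnfrsf25 changed by −0.84, −1.09, −2.05 and −1.53 (SE 0.21). Arc, Fos, Egr2, Klf10, Junb, Nr4a1 and Tnfrsf25 were called in all 4 comparisons also without the 16 libraries with the highest olfactory bulb scores, a choice made after seeing the data.

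**Figure D2:**
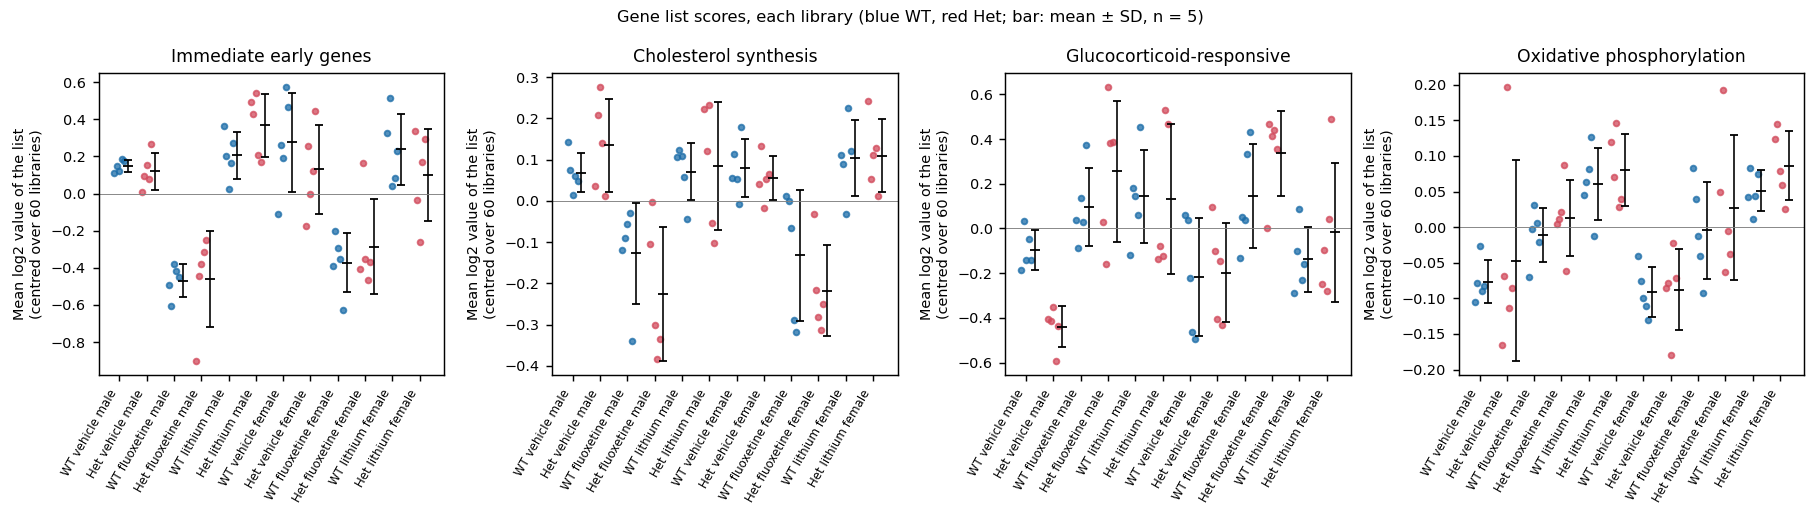
Score of 4 gene lists (mean centered log2 value, vertical axes) in each library of the 12 groups (horizontal axes), with WT in blue, Het in red, and the group mean ± SD of 5 libraries as a bar. Immediate early gene scores were below 0 in all fluoxetine libraries except Het fluoxetine female replicate 2, at 0.162.

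Genes of cholesterol synthesis were lower with fluoxetine. Of 24 members 1 was lower in WT males, 4 in WT females, 17 in Het males and 15 in Het females, with none higher, and 8, 14, 19 and 17 were lower adjusted over the list alone. Medians were −0.19, −0.20, −0.34 and −0.28 (adjusted p = 8.81e-10, 1.90e-08, 3.62e-12 and 3.02e-09, and adjusted p = 0.724 or more with an estimated correlation). Insig1, a sterol sensor of the endoplasmic reticulum, changed by −0.31, −0.36, −0.42 and −0.39 (SE 0.07), in 5 of 5 libraries of each. The isomerase gene Idi1 changed by −0.43 in WT females, −0.68 in Het males and −0.46 in Het females (SE 0.11). In WT males it stood at −0.30 (adjusted p = 0.216). The WT female call was lost without the 16 libraries. Fluoxetine libraries with glucocorticoid scores of at least 0.333 had cholesterol scores of −0.384 to −0.216, and the others −0.12 to 0.011. Glucocorticoid-responsive genes moved the other way. Among 17 of them 11 were higher in Het males and 6 in Het females, 12 and 10 adjusted over the list alone, with medians of 0.57 and 0.33 (adjusted p = 1.66e-07 and 1.20e-06, and adjusted p = 0.724 and 0.774 with an estimated correlation). This list was the one lower in Het vehicle males, the group the Het males are compared with (scores −0.595 to −0.351), and Het fluoxetine males stood at 0.031 and −0.158 in replicates 1 and 2 and at 0.383 to 0.633 in the others. In WT females the median was 0.30 (adjusted p = 4.92e-05, and adjusted p = 0.949 with an estimated correlation) with no member called over all genes and 5 adjusted over the list alone, and in WT males 0.24 (adjusted p = 0.0563), not called. Scores of WT fluoxetine females were 0.333 and 0.432 in replicates 4 and 5 and −0.133 to 0.049 in the others. Fkbp5, a co-chaperone of the glucocorticoid receptor, rose by 1.04 ± 0.17 in Het males and 0.90 ± 0.17 in Het females, and stood at 0.50 and 0.58 in WT males and females without being called in a single sex. Averaged over both sexes it was called in WT mice (0.54, adjusted p = 0.00191).

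In WT males 238 genes were called with fluoxetine (44 higher, 194 lower) and in WT females 446 (108 higher, 338 lower), and the average over both sexes had 1461 (560 higher, 901 lower). Beside the genes above, Nr4a3 (−1.19 and −1.23) and the kinase gene Sik1 (−1.08 and −0.94) fell in both sexes. In males the corepressor gene Nab2 (−0.68 ± 0.09) and the ephrin ligand gene Efnb1 (−0.48 ± 0.07) were lower, and Nemp2 (0.74 ± 0.11) and mt-Nd3 (0.68 ± 0.16), a mitochondrially encoded subunit of complex I, were higher. In females Lyve1, a receptor for hyaluronan on lymphatic vessels and macrophages, rose by 1.002 ± 0.206 and Edn1, the endothelin peptide gene, by 0.81 ± 0.19. The serotonin receptor gene Htr2a rose in WT females (0.35 ± 0.08) and in Het males and females (0.40 and 0.32). Without the 16 libraries it was called in Het females only. Of 66 autism risk genes 1 was called in WT males, Kdm6b at −0.58 ± 0.14, and 3 in WT females, Kdm6b (−0.73), Kmt2a (−0.52) and Kdm5b (−0.25). That list's medians were −0.05 and −0.04 (adjusted p = 0.00250 and 0.00416, and adjusted p = 0.949 with an estimated correlation). Fam205a2 was listed at 0 in the 5 WT fluoxetine females against 399 ± 123 in WT vehicle females, a gene with near-identical copies whose level is uncertain.

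Other lists called in WT mice had an adjusted p = 0.949 with an estimated correlation. Nuclear-encoded genes of oxidative phosphorylation were higher by 0.06 in males and 0.07 in females, with none of 77 called (adjusted p = 9.91e-06 and 4.29e-08), and cytosolic ribosomal proteins by 0.09 and 0.10 (adjusted p = 3.02e-09 and 1.00e-08). Mitochondrially encoded genes were higher in males (0.14, adjusted p = 0.0271) and heat shock genes in females (0.15, adjusted p = 0.00940). Beside these, myelin markers stood at −0.41 and −0.43 (adjusted p = 0.00250 and 0.00634) and olfactory bulb markers at −0.87 and −0.99 (adjusted p = 0.0231 and 0.0227). Without the 16 libraries with the highest olfactory bulb scores, 185 of the 238 male genes and 86 of the 446 female genes were called, and all of them kept their direction. Edn1 and Fam205a2 were among the female genes that lost their call. Without WT fluoxetine male replicate 2 the male count was 151 and without WT vehicle female replicate 5 the female count 177. For the sex average quantile normalization gave 800 higher and 846 lower genes and rescaling 387 and 1028.

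In Het males fluoxetine changed 4037 genes (2134 higher, 1903 lower). The galactosaminyltransferase gene Galnt15 rose by 1.17 ± 0.16, the hypoxia-inducible factor gene Hif3a by 0.96 ± 0.19 and Zbtb16, a glucocorticoid-induced transcription factor, by 0.64 ± 0.12. Aplnr, the apelin receptor, changed by −1.66 ± 0.29, the kinase gene Stk40 by −0.64 ± 0.07 and Fabp7, a fatty acid binding protein of glial progenitors, by −1.90 ± 0.60. Of 31 presynaptic release genes 10 rose and none fell (median 0.11, adjusted p = 0.00181), among them Snap25 (0.37 ± 0.09), Sv2b (0.42 ± 0.08) and Nsf (0.30 ± 0.07). This list was lower in Het vehicle males, the group compared with, and its mean scores were −0.0774 there, 0.0313 in WT vehicle males and 0.0615 in Het fluoxetine males. Among 77 oxidative phosphorylation genes 18 rose and 1 fell (median 0.05, adjusted p = 0.000955), with Atp5a1 at 0.25 ± 0.05 and Uqcrc2 at 0.31 ± 0.06. Microglia markers were lower (median −0.26, adjusted p = 0.00389), with 7 of 20 called, such as P2ry12 (−0.56 ± 0.16, 4 of 5 libraries) and Aif1 (−0.77 ± 0.18). Targets of Wnt signaling were lower (median −0.19, adjusted p = 0.0231), with 3 of 18 called, namely Axin2 (−0.25 ± 0.06), Lef1 (−0.55 ± 0.14) and Nkd1 (−0.36 ± 0.10). These lists had an adjusted p = 0.949 with an estimated correlation. Olfactory bulb markers stood at −0.88 beside them (adjusted p = 0.205). Without the 16 libraries 287 of the 4037 genes were called and 4034 kept their direction, with Axin2 and Fabp7 among those not called. With 4 tissue scores in the model 1636 were called and all kept their direction. A fit of only the groups compared called 608, Het fluoxetine male replicate 3 left out gave 2323, and rescaling gave 1108 higher and 2801 lower.

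In Het females fluoxetine changed 2691 genes (1260 higher, 1431 lower). Oligodendrocyte and myelin markers were higher (median 0.80, adjusted p = 1.21e-07, and adjusted p = 0.949 with an estimated correlation). Among 24 of them 12 were called and 18 were higher adjusted over the list alone, with Mobp at 1.62 ± 0.42, Mal at 1.49 ± 0.37 and Mog at 1.37 ± 0.40. With 4 tissue scores in the model, 1 of them the myelin score itself, these were 0.32, 0.37 and 0.15. Myelin markers were the list lower in Het vehicle females, the group these are compared with. Leptomeningeal markers were lower (median −0.50, adjusted p = 6.86e-07), with 10 of 21 called, among them Lum (−0.91 ± 0.23) and Col3a1 (−0.84 ± 0.22), and so were endothelial markers (−0.25, adjusted p = 0.000147), with 8 of 19 lower and Slc2a1 higher. Mural cell markers (−0.18, adjusted p = 0.0141), with 4 of 12 called such as Rgs5 (−0.54 ± 0.14), and microglia markers (−0.25, adjusted p = 0.00420), with 1 called, were lower too, the mural list turning direction with 2 or 4 tissue scores and the microglia list with 2, and these 4 lists had an adjusted p = 0.949 with an estimated correlation. Serotonin receptor and handling genes were higher (median 0.27, adjusted p = 0.0227), with Htr1a (0.41 ± 0.13), Htr2a (0.32 ± 0.08) and Htr2c (0.91 ± 0.30) called of 16. Htr2c stood at 951 ± 582 counts in the Het vehicle females compared with, against 1395 ± 178 in WT vehicle females (SD, n = 5), and lithium gave 0.75 against the same group without a call. Wnt targets were lower (−0.26, adjusted p = 0.000760), with 5 of 18 called, such as Axin2 (−0.36 ± 0.06) and Tcf7 (−0.64 ± 0.18). For both lists the adjusted p = 0.724 with an estimated correlation.

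Sgk1, a glucocorticoid-induced kinase, rose by 0.70 ± 0.12 in Het females (adjusted p = 5.83e-05), and Tfap2d, a developmental transcription factor, by 3.30 ± 0.71 from 37.1 ± 47.9 to 145 ± 83.1 counts (SD, n = 5). Cytosolic ribosomal proteins were higher (median 0.12, adjusted p = 2.22e-08), with 22 of 79 higher and 1 lower, as were oxidative phosphorylation genes (0.09, adjusted p = 2.01e-08), with 19 of 77 higher and Ndufv2 at 0.38 ± 0.07. Both had an adjusted p = 0.949 with an estimated correlation. Without the 16 libraries with the highest olfactory bulb scores 1612 of the 2691 genes were called, and with 4 tissue scores 938, with 2690 in the same direction under each. Without Het vehicle female replicate 3 the count was 1298. Over both sexes the Het average had 5853 genes (3003 higher, 2850 lower), and rescaling gave 2027 higher and 3539 lower.

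**Figure D3:**
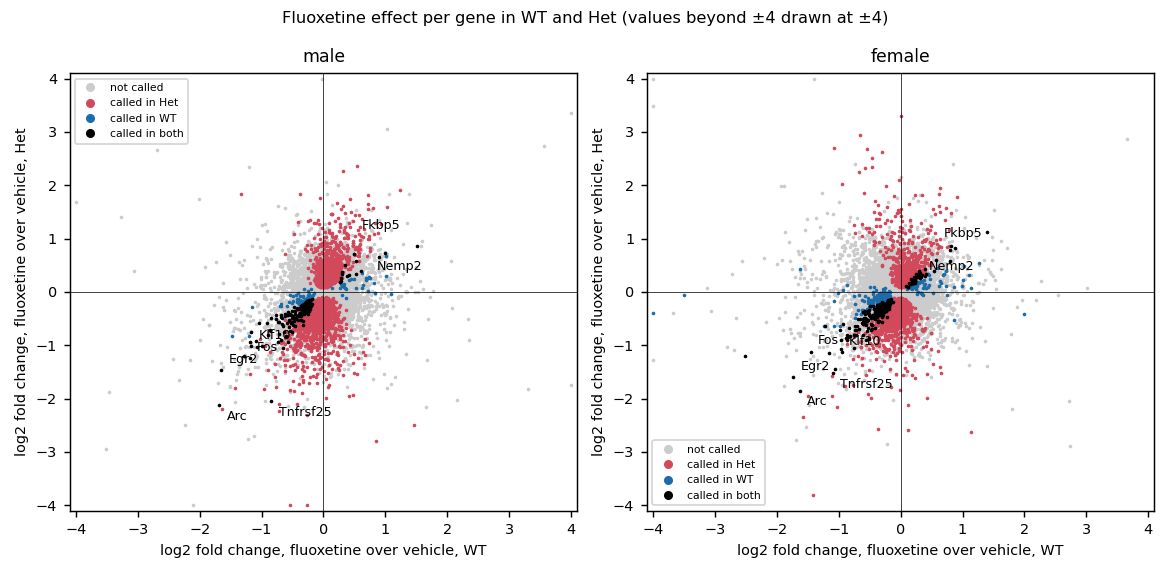
Log2 fold change of fluoxetine over vehicle for each tested gene in WT (horizontal axis) and Het (vertical axis), males left and females right, with values beyond ±4 drawn at ±4. Colors mark genes called in Het, in WT or in both. Arc lay at −1.68 and −2.13 in males and at −1.63 and −1.85 in females.

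Whether fluoxetine acted differently in Het and WT mice was tested by the interaction. In males it was called for 165 genes (60 higher, 105 lower in Het relative to WT). That count fell to 1 without the 16 libraries with the highest olfactory bulb scores, 7 in a fit of only the groups compared and 49 with 2 tissue scores. Slc39a2 had the smallest p, with −0.92 in Het against 0.16 in WT males (difference −1.07 ± 0.18, adjusted p = 0.00163). Arhgef1 differed by −0.43 ± 0.08 (adjusted p = 0.00645), Acrbp by −1.17 ± 0.22 (adjusted p = 0.00760) and Hsf1, the heat shock transcription factor, by −0.33 ± 0.07 (adjusted p = 0.0168). Quantile normalization gave 25 higher and 93 lower and rescaling 15 higher and 203 lower. The count was 9 without Het vehicle male replicate 1 and 695 without WT fluoxetine male replicate 5. In females limma called 0 genes for it, with 2349 at an unadjusted p under 0.05, edgeR and voom 0, DESeq2 18 and array weights 291. Tnfrsf25 was among the 165 (difference −1.21 ± 0.29, adjusted p = 0.0354). Arc (−0.44 ± 0.33 in males, adjusted p = 0.498), Fos, Egr2, Klf10, Insig1, Fkbp5 (0.54 ± 0.24 in males, adjusted p = 0.234) and the myelin gene Mobp (1.99 ± 0.60 in females, adjusted p = 0.221) were not shown to differ between genotypes in their response. No gene was shown to respond differently in the 2 sexes of WT mice (limma 0 genes, 477 unadjusted, edgeR and voom 0, DESeq2 4). In Het mice 2 genes without proper names were called, Gm37460 and Gm48700, with 2170 at an unadjusted p under 0.05.

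Lithium lowered Ctnnb1 in every group. This gene encodes beta-catenin, a protein that lithium's target GSK3 marks for breakdown. The mRNA changed by −0.23 ± 0.04 in WT males (adjusted p = 0.0101), −0.22 in WT females (adjusted p = 0.0226), −0.34 in Het males (adjusted p = 5.16e-07) and −0.25 in Het females (adjusted p = 0.000687), in 5 of 5 libraries of each. In Het males that was from 19898 ± 401 to 15684 ± 689 normalized counts (SD, n = 5). Over both sexes it changed by −14.7% in WT and −18.6% in Het mice. The creatine transporter gene Slc6a8 rose by 0.20 ± 0.04 in WT males, 0.27 in Het males and 0.25 in Het females and stood at 0.13 in WT females (adjusted p = 0.175). Vgf, a neuropeptide precursor gene, rose in WT males (0.48 ± 0.10, adjusted p = 0.0374) and Het males (0.61 ± 0.10, adjusted p = 0.000818). Rims1, a scaffold of the presynaptic active zone, fell in WT females (−0.51 ± 0.10), Het males (−0.42) and Het females (−0.63, adjusted p = 0.000322). Without the 16 libraries with the highest olfactory bulb scores, the calls were lost for Ctnnb1 in WT females, Slc6a8 and Vgf in Het males, and Rims1 in WT females and Het males. Impa1, the inositol monophosphatase that lithium inhibits, rose in Het males (0.22 ± 0.05, adjusted p = 0.00981) and was not called with lithium in the other 3 groups. Fluoxetine raised it too, by 0.24 in Het males (adjusted p = 0.000499) and 0.18 in Het females (adjusted p = 0.00735), whereas Gsk3b, Inpp1 and Bdnf were not called with either drug.

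**Figure D4:**
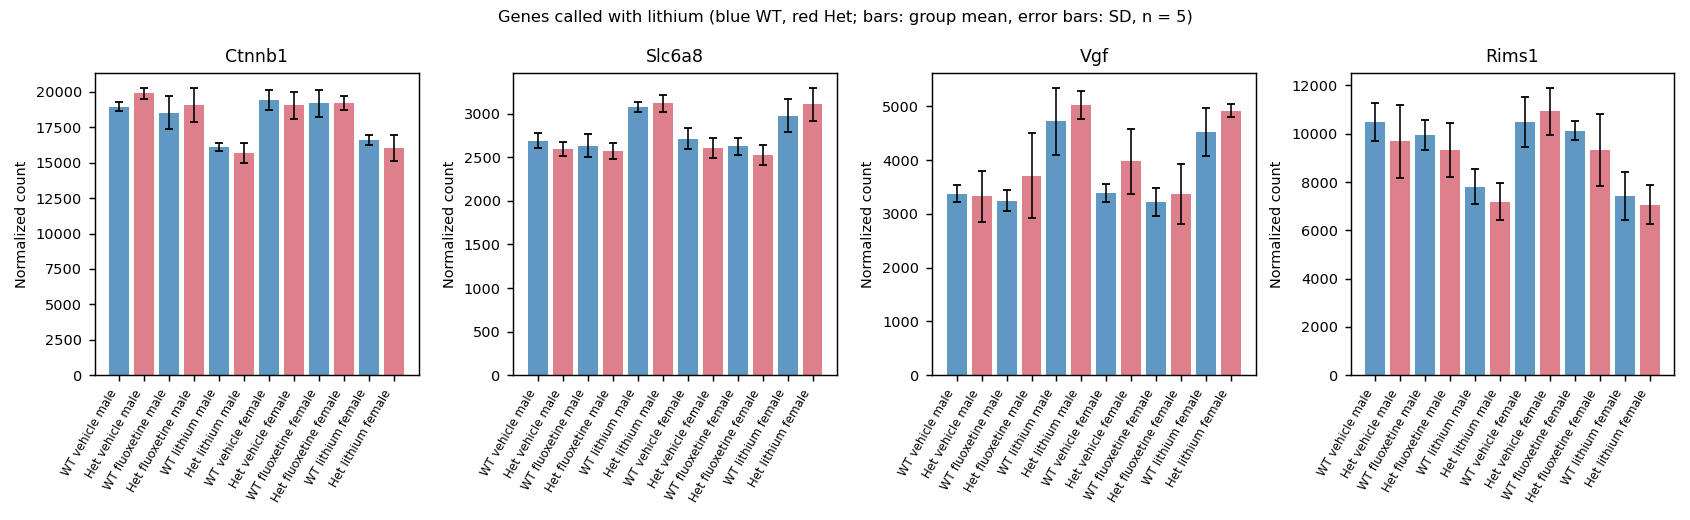
Normalized counts of Ctnnb1, Slc6a8, Vgf and Rims1 (vertical axes, from 0) in the 12 groups (horizontal axes), as group means (bars, WT blue, Het red) with the SD of 5 libraries. Ctnnb1 means with lithium lay between 15684 and 16592, and with vehicle between 18955 and 19898.

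Nuclear-encoded genes of oxidative phosphorylation were higher with lithium in every group. Their medians over 77 genes were 0.13 in WT males, 0.13 in WT females, 0.14 in Het males and 0.16 in Het females (adjusted p = 2.32e-27, 6.91e-26, 5.95e-17 and 2.87e-31). Called over all genes were 0, 2, 9 and 13 of them, all higher, and adjusted over the list alone 28, 35, 30 and 45. Examples were Atp5g3 (0.20 ± 0.04 in WT females and in Het males), Uqcrfs1 (0.28 ± 0.06 in WT females), Sdhd (0.26 ± 0.05 in Het males) and Cox7b (0.35 ± 0.08 in Het females). The adjusted p was 0.685, 0.685, 0.724 and 0.542 with an estimated correlation, and 0.0410, 0.0341, 0.0376 and 0.00623 with fry. Erythrocyte genes had medians of 0.79, 0.63, 0.90 and 0.64 over 5 genes (adjusted p = 2.90e-05, 0.00375, 0.000533 and 0.00751, and adjusted p = 0.724 or more with an estimated correlation). None was called in a single sex, 5 and 4 were higher adjusted over the list alone in WT and Het males, and as an average over both sexes Hbb-bs rose by 0.79 in WT and 0.86 in Het mice. Cytosolic ribosomal proteins were higher by 0.09, 0.08 and 0.08 in WT males, WT females and Het females (adjusted p between 2.98e-09 and 2.22e-08, and adjusted p = 0.949 with an estimated correlation), with no member called.

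In WT mice lithium changed 14 genes in males (5 higher, 9 lower; 1619 at an unadjusted p under 0.05) and 21 in females (15 higher, 6 lower; 2010 unadjusted), and 529 as an average over both sexes (339 higher, 190 lower). Males had more of the synaptic adhesion gene Lrfn2 (0.49 ± 0.10) and less of the zinc exporter gene Slc30a1 (−0.31 ± 0.07) and of Lama2 (−0.40 ± 0.08), a laminin chain. Females had more of the tubulin gene Tuba4a (0.36 ± 0.08) and less of Atp11b (−0.51 ± 0.10), a phospholipid flippase. Calls lost without the 16 libraries were Lrfn2 in males and Tuba4a, Atp11b, Uqcrfs1 and Atp5g3 in females. Heat shock genes were higher in both, by 0.10 (adjusted p = 0.0126) and 0.19 (adjusted p = 2.01e-08, and adjusted p = 0.724 with an estimated correlation), with 0 and 3 of 22 adjusted over the list alone. In males glucocorticoid-responsive genes were higher (0.21, adjusted p = 0.000885). Circadian, inhibitory synapse and autism risk genes were lower (−0.08, −0.06 and −0.05, adjusted p = 0.0391, 0.0273 and 0.000152). In females autism risk genes were lower (−0.04, adjusted p = 0.0401), and turned direction without the 16 libraries. Precursors of oligodendrocytes had lower markers in both, at −0.06 (adjusted p = 0.0499) and −0.14 (adjusted p = 0.00250, and adjusted p = 0.774 with an estimated correlation). Other tissue markers stood at −0.53 for choroid plexus, −0.16 for mural cells and −0.13 for leptomeninges in males (adjusted p = 0.0157, 0.0157 and 0.0258) and at −0.26 for myelin in females (adjusted p = 0.0203). Choroid markers turned direction without the 16, which here removed only WT vehicle male replicate 2 (choroid score 2.831, others up to 0.283). All lists with no value given had an adjusted p = 0.949 with an estimated correlation. Quantile normalization gave 6 higher and 7 lower in males. No gene was called without WT lithium male replicate 3 in males or without WT lithium female replicate 5 in females.

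In Het males lithium changed 356 genes (256 higher, 100 lower; 3487 unadjusted) and in Het females 112 (79 higher, 33 lower; 2462 unadjusted), and 1627 as an average over both sexes (944 higher, 683 lower). Males had more of Pvalb, the calcium-binding protein of fast-spiking interneurons (0.84 ± 0.17), and of Rasl11a (0.97 ± 0.17). Females had more of Serpina3n, an inflammation-induced protease inhibitor (0.92 ± 0.22), and of the ATP synthase subunit genes Atp5mpl (0.64 ± 0.13) and Usmg5 (0.46 ± 0.09). Slc35f6 rose in both (0.35 and 0.32, SE 0.05), and Tuba4a too (0.53 in males and 0.35 in females), though the latter was not called in males without the 16 libraries with the highest olfactory bulb scores or in females with 4 tissue scores. Glucocorticoid-responsive genes were higher in males (median 0.38, adjusted p = 1.15e-10, and adjusted p = 0.724 with an estimated correlation), with 4 of 17 called and 16 adjusted over the list alone, such as Fkbp5 (0.65 ± 0.17), which was not called with 4 tissue scores (adjusted p = 0.208) or without the 16 libraries (adjusted p = 0.583). Male scores were 0.531 and 0.467 in replicates 4 and 5 and −0.137 to −0.078 in the others. In females the list stood at 0.13 (adjusted p = 0.0397), and was not called without Het lithium female replicate 5 (adjusted p = 0.587) or 4, without Het vehicle female replicate 3 or 5, with 2 or 4 tissue scores, or without the 16 libraries. In males immediate early genes were higher (0.18, adjusted p = 0.000280), with Dusp1 (0.62 ± 0.15) and Rasl11a called of 28. Wnt targets were lower in both, at −0.16 (adjusted p = 0.0337) and −0.22 (adjusted p = 0.00159, and adjusted p = 0.724 with an estimated correlation), with no member called and 5 lower in females adjusted over the list alone. Heat shock genes were higher in females (0.15, adjusted p = 1.01e-05, and adjusted p = 0.779 with an estimated correlation), with Chac1 at 0.51 ± 0.12. Where not given, the adjusted p = 0.949 with an estimated correlation.

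Cell type markers moved in these Het lithium mice as well, each with an adjusted p = 0.949 with an estimated correlation. Microglia (−0.25 and −0.13, adjusted p = 6.95e-05 and 0.0137), endothelial (−0.17 and −0.16, adjusted p = 0.0145 and 0.00751), astrocyte (−0.12 and −0.13, adjusted p = 0.0305 and 0.00844) and leptomeningeal markers (−0.30 and −0.35, adjusted p = 0.000104 and 1.20e-06) were lower in males and females. With tissue scores in the model some of these lists turned direction and were no longer called, the endothelial and astrocyte lists in males with 4 scores, the microglia and endothelial lists in females with 2 or 4, and the astrocyte list in females with 2 (adjusted p up to 0.988). Mural cell markers (−0.27, adjusted p = 0.000483) and oligodendrocyte precursor markers (−0.17, adjusted p = 0.00940) were lower in males. Females had myelin markers at 0.35 and olfactory bulb markers at −1.55 (adjusted p = 0.00400 for both), and cytosolic ribosomal proteins as given above. Without the 16 libraries 3 of the 356 male genes and 105 of the 112 female genes were called, and all kept their direction, among 4 and 942 genes called in all. Pvalb, Rasl11a and Dusp1 in males and Chac1 in females were among those that lost their call. In a fit of only the groups compared, limma called 92 genes in males and 0 in females. Without Het vehicle male replicate 1 the male count was 71, without Het vehicle male replicate 3 it was 1103, and without Het vehicle female replicate 3 the female count was 7.

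Lithium's effect was not shown to differ between genotypes or sexes for any gene. For the genotype difference limma called 0 in males (689 at an unadjusted p under 0.05) and 0 in females (386), with edgeR and voom at 0 and DESeq2 at 1 in each. For the sex difference it called 0 in WT (419) and 0 in Het mice (1030), with edgeR, voom and DESeq2 at 0. The sex by genotype interaction under vehicle had 0 called genes (1207 unadjusted, edgeR and voom 0, DESeq2 1). Between WT vehicle males and females 12 genes differed (7 higher in males, 5 lower). Kdm5d, Uty, Eif2s3y and Ddx3y of the Y chromosome were higher in males and Xist lower, and the X-linked genes Eif2s3x (−0.52 ± 0.05), Kdm5c (−0.35 ± 0.07) and Kdm6a (−0.33 ± 0.07), which escape X inactivation, were lower. The autosomal protocadherin gene Pcdha9 was higher in males (0.61 ± 0.12, adjusted p = 0.0176).

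**Figure D5:**
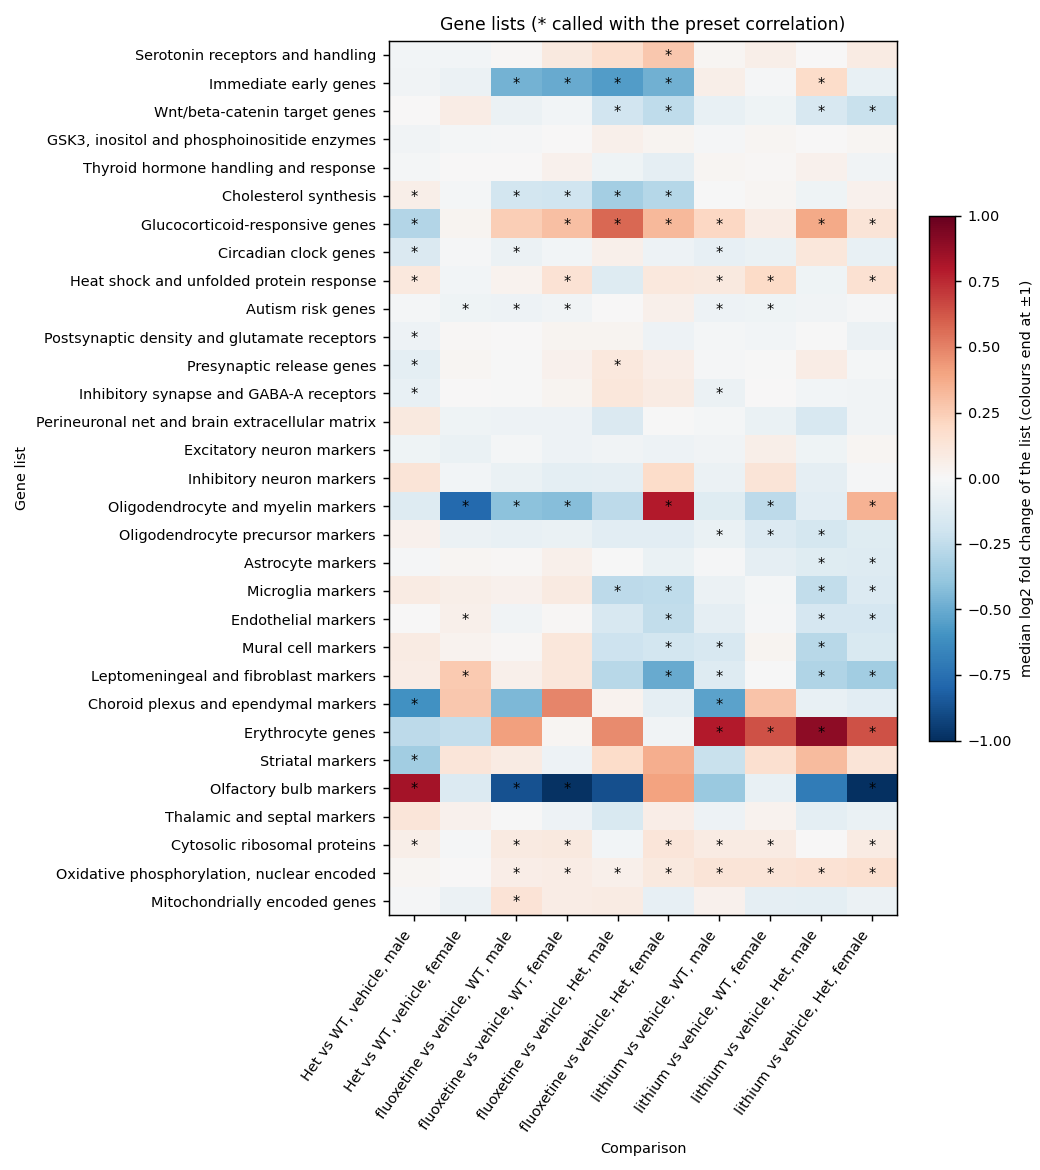
Median log2 fold change (color, ending at ±1) of the 31 gene lists (vertical axis) in the 10 main comparisons (horizontal axis), with a star where a list was called with the preset correlation. Oxidative phosphorylation was higher in all 8 drug comparisons, by 0.05 to 0.16.

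In all, 94 of 310 list tests were called with the preset correlation, none with an estimated correlation after adjustment (smallest adjusted p = 0.115) and 16 with fry. No called list changed direction under quantile normalization or rescaling. Among the 212 results for named genes in the main comparisons, no called result changed direction either. Other named genes and results that were not called were not scored for this. Never called were 6 lists, with medians between −0.03 and 0.05 for GSK3 and inositol genes, −0.09 and 0.04 for thyroid hormone genes, −0.16 and 0.10 for perineuronal net genes, −0.07 and 0.06 for excitatory neuron markers, −0.10 and 0.18 for inhibitory neuron markers and −0.15 and 0.12 for thalamic and septal markers. Slc6a4, the serotonin transporter that fluoxetine blocks, was not among the genes tested.

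Whether a drug's effect in Het mice ran against the genotype effect was asked across 17807 genes. The correlations were −0.566 and −0.516 for fluoxetine in males and females and −0.538 and −0.423 for lithium. Both comparisons share the Het vehicle libraries, and simulations of unchanged groups gave −0.494, −0.486, −0.487 and −0.483, with 52, 84, 69 and 147 of 200 as far from 0. The covariance differed from the simulated one by −0.0249, −0.0162, −0.0113 and −0.0012. With the vehicle libraries split between the comparisons the correlations were −0.18, −0.135, −0.087 and −0.018. Effects of fluoxetine and lithium correlated at 0.499, 0.461, 0.594 and 0.482 in WT males, WT females, Het males and Het females, against 0.497, 0.515, 0.488 and 0.50 simulated, covariance differences of 0.0021, 0.0029, 0.0338 and 0.0172, and 0.069, 0.095, 0.227 and 0.142 with split vehicles.

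Comparisons that share no library correlated positively, and for 4 of the 8 over 5% of simulations lay as far from 0. They can share litters, so they need not be independent. Fluoxetine effects in WT and Het mice correlated at 0.273 in males (18 of 200 simulations) and 0.136 in females (62 of 200). Between males and females they correlated at 0.311 in WT (2 of 200) and 0.326 in Het mice (0 of 200). For lithium the values were 0.232 (19 of 200) and 0.279 (5 of 200) between genotypes, and 0.202 (13 of 200) and 0.277 (1 of 200) between sexes. Fluoxetine lowered 138 genes in both WT and Het males, against 20.73 if calls were independent, and 190 in both female groups (27.16). In the same direction in Het mice were 231 of the 238 genes called in WT males and 425 of the 446 called in WT females. Lithium's 14 genes in WT males all had the same direction in Het males, where 5 were called higher and 5 lower, and 19 of the 21 genes of WT females in Het females.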

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

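Tests chosen only after their result was seen were the ranking of left-out male libraries, the tests of genes near Chd8, and the splits for interactions, sex averages and male against female mice.

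Glud1 and Entpd4 were lower in Het mice, and single libraries stood apart from their group toward the other genotype. Glud1 was at 5177 in WT vehicle female replicate 1 (the other 4 libraries at 6596 to 6774) and at 4842 in WT vehicle male replicate 4 (others 6592 to 7044), and at 6419 in Het fluoxetine female replicate 2 (others 4704 to 4999.65). Entpd4 was at 2780 in WT fluoxetine female replicate 2 (others 3628 to 3853), 2664 in WT lithium male replicate 5 (others 3719 to 3835) and 2752 in WT vehicle male replicate 5 (others 3669 to 3787), and at 3114 in Het lithium male replicate 3 (others 2692 to 2783).

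When Het was set against WT over the 6 combinations of drug and sex, a comparison added after seeing the data, 11 of 328 tested genes within 20 Mb of Chd8 were called against 262 of 17478 elsewhere (Fisher's exact test, two-sided p = 0.0187). That count includes the genes that prompted it. Without Glud1, Entpd4 and the 2 genes overlapping Entpd4 it was 7 of 324 (two-sided exact p = 0.349; 0.0926 to 0.546 over other windows). For these other genes, linked variants of another strain cannot be told apart from an effect of the Chd8 allele on its neighbors, which stays open as the biological explanation. For Glud1 and Entpd4 themselves, the allele as sole control is argued against. Glud1 was nearer the other genotype in 2 WT libraries and 1 Het library, and Entpd4 in 3 WT libraries, with no library in both. Linked variants, alone or beside an effect of the allele, stay open for these 2 genes. Other readings are argued against, since 6 libraries had Glud1 or Entpd4 nearer the mean of the other genotype while Chd8 was nearer its own, against Chd8 level as the sole control of these genes, and 0 of the 6 had Chd8 out of place, against mislabelled libraries. Sncg, next to Glud1, was nearer the other genotype in 9 libraries, among them the 3 of Glud1, and Gm16867, beside Entpd4, in 6, among them the 3 of Entpd4.

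Fluoxetine called 4037 genes in Het and 238 in WT males. Tissue of neighboring regions cannot be told apart from a genotype effect, since leaving out the 3 Het vehicle and 2 Het fluoxetine males with high olfactory bulb scores gave 302 genes, rank 15 from the lowest among 100 ways of leaving out as many (81 to 4986, median 1376.5). Unusual Het vehicle males as the sole cause are argued against, because Het fluoxetine against WT vehicle males still called 1415 genes, while WT fluoxetine against Het vehicle males called 563. The 165 interaction genes of males were set among 100 splits of the 20 libraries, the real one included, of which 6 gave as many, so chance was not excluded. Genotype therefore stays open as the biological explanation.

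Oxidative phosphorylation genes rose with lithium in all 4 comparisons. Transcript length, GC content and level are argued against, as the list median was at percentile 100 of 10000 matched random lists in each. Matched genes rose too, by 0.05 and 0.07 in WT and 0.04 and 0.07 in Het males and females. Neighboring tissue and myelin are argued against, as 4 tissue scores left at least 0.785 times each median. Litter and low vehicle libraries stay open. Against the same vehicles fluoxetine raised the score by 0.076 in WT and 0.088 in Het mice (lithium 0.14, 0.151). A part due to lithium remains a hypothesis.

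Single libraries also stood apart in other measures. WT fluoxetine male replicate 4 had 26.01 M reads (others 30.46 to 31.65 M). Het fluoxetine female replicate 2 had an immediate early gene score of 0.162 (others −0.466 to −0.353), and Het fluoxetine female replicate 1 a glucocorticoid score of 0.001 (others 0.355 to 0.467). The oxidative phosphorylation score was 0.197 in Het vehicle male replicate 3 (others −0.166 to −0.068) and the myelin score 0.623 in WT vehicle male replicate 1 (others 0.014 to 0.181). Striatal scores were 1.31 in Het fluoxetine male replicate 5, 1.451 in WT fluoxetine female replicate 2, 2.257 in WT fluoxetine male replicate 3 and 1.556 in WT vehicle male replicate 1, where no other library of these groups exceeded −0.112. Leptomeningeal scores were 0.587 in Het fluoxetine male replicate 1 and 0.017 in Het lithium male replicate 2, and choroid plexus scores 0.999 in Het vehicle female replicate 1 and 2.831 in WT vehicle male replicate 2. In all, 20 of 180 group and measure combinations had such a library, and chance gives about 1 in 20.

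Differences in response between groups were called for the 165 genes above and for 2 genes in the sex by fluoxetine interaction of Het mice, and chance was excluded for neither count. The Het minus WT difference of the fluoxetine effect in males was −1.07 for Slc39a2, −0.43 for Arhgef1, −1.17 for Acrbp, −0.33 for Hsf1, −0.39 for Ascc2, −0.56 for Crocc, −0.48 for Fam193b and −0.47 for Lrrc45.

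Other splits of the same libraries were fitted, 100 per comparison with the real one included. For fluoxetine only the real split gave as many genes in WT males (highest other 2), WT females (41), Het males (3672) and Het females (1196). No other split tried reached the real counts, though in Het males 3672 came near the real 4037. The splits exchange single mice, so they cannot exclude a chance difference between litters. For lithium 1 split gave as many in WT males (highest other 1), 1 in WT females (2), 4 in Het males (710) and 3 in Het females (692), and for genotype under vehicle 2 in males (4) and 3 in females (548). For genotype under fluoxetine 9 splits did in males (1937), so chance was not excluded, and 3 in females (524), and under lithium 8 in males (13), so chance was not excluded, and 1 in females (1). Sex averages had 1 for genotype (3) and 1 each for fluoxetine in WT (250) and Het mice (3266) and lithium in WT (2) and Het mice (555). Interactions had 6 for genotype and fluoxetine in males (2010) and 15 for sex and fluoxetine in Het mice (3179), so chance was not excluded for either. All 100 gave at least the 0 genes of the other interactions, with up to 905 for genotype and fluoxetine in females, 789 for genotype and lithium in females, 555 for sex and lithium in Het mice and 3 or fewer in the rest, and male against female mice had 1 (8). Splits with several times the real count point to a structure of the samples, whose source was not tested.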

How the results depend on the processing

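Chosen after seeing the data were edgeR, DESeq2, limma-voom, the 4 tissue scores and the fit without the 16 libraries with an olfactory bulb score above 1; the other alternatives were planned. The 212 results for named genes, each a gene in 1 comparison, included Chd8 in the drug comparisons, where it was not called. Those that were called kept their direction under every alternative that gave them a value. Below, a result is unchanged when called in both fits or, as for Chd8 with a drug, in neither. Unchanged were 212 results with a pseudocount of 0.5 or a minimum of 50, 211 without a filter or with array weights and 210 with a pseudocount of 5. The replicate number as a block left 207 unchanged, DESeq2 202, quantile normalization 200, edgeR 199, rescaling 194 and voom 189. With 2 tissue scores 164 were unchanged, with 4 scores 154, without the 16 libraries 123 and in a fit of only the groups compared 113. With single libraries left out, 1449 cases were unchanged and 671 lost their call. List results stayed called in 829 such cases, not in 110 and turned in 1. Of the 94 called list results 86 held with quantile normalization, 92 after rescaling, 61 with 2 and 54 with 4 tissue scores, 69 without the 16 libraries, 15 with fry and 0 with an estimated correlation. With 2 or 4 scores the lists used as covariates, and without the 16 libraries the olfactory bulb list, have no value. Of 5 libraries per group, the 16 left out were 3 each of Het vehicle males and Het fluoxetine females, 2 each of Het fluoxetine males, Het vehicle females, WT vehicle females and WT lithium females, and 1 each of WT vehicle males and Het lithium males, so that 2 to 5 remained per group. The depth of 24.05 M reads or more leaves the spread between mice, not counting error, as the limit for genes of high counts. Where no cause is given below, the cause was not tested.

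Quantile normalization called 1 gene for Het against WT vehicle males (3 in the main test), 1 for females (4), 12 for Het against WT fluoxetine females (7) and 6 for the genotype average (10). Rescaling called 0 and 2 for genotype in vehicle males and females, 8 and 36 for lithium in WT males and females (14 and 21) and 3 for genotype in fluoxetine females. A minimum of 50 called 42 for lithium in WT females and 0 for the sex by fluoxetine interaction in Het mice (2). It raised the fluoxetine correlation between sexes in WT mice to 0.435 and the lithium correlations between genotypes to 0.402 in males and between sexes in WT mice to 0.302, where fewer low genes entered.

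Array weights called 66 and 25 genes for genotype in vehicle males and females, 708 and 1127 for fluoxetine in WT males and females, 379, 721, 1973 and 306 for lithium in WT males, WT females, Het males and Het females, and 96 and 375 for genotype in fluoxetine males and females. They called 5 for genotype in lithium males and 5 in lithium females, 26 for the genotype average, 2671 for the WT fluoxetine average, 2256 and 2731 for the WT and Het lithium averages, 869 and 291 for the genotype by fluoxetine interaction in males and females, and 1 for the sex by fluoxetine interaction in Het mice. A fit of only the groups compared, which has fewer libraries to estimate the spread, called 0 and 2 for genotype in vehicle males and females, 608 and 874 for fluoxetine in Het males and females, 66, 92 and 0 for lithium in WT females, Het males and Het females, 1 and 0 for genotype in fluoxetine males and females, 5 for the genotype average, 1285 and 1059 for the WT and Het lithium averages, and 7 and 0 for the genotype by fluoxetine interaction in males and the sex by fluoxetine interaction in Het mice.

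Same-number correlations averaged −0.0497 to 0.1153. From 0 to 4 of 5 pairs (4 for lithium in Het males) matched best by number, so pairing stays open. Replicate blocks called 5 and 4 genes for genotype in vehicle males and fluoxetine females and 41 for lithium in WT females.

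With 2 tissue scores the counts were 9 and 2 for genotype in vehicle males and females, 946 and 949 for fluoxetine in WT and Het females, 30, 106 and 198 for lithium in WT males, WT females and Het males, 115 for genotype in fluoxetine males, 2202 and 3480 for the WT and Het fluoxetine averages, 837 and 689 for the lithium averages, and 49 and 24 for the genotype by fluoxetine interaction in males and the sex by fluoxetine interaction in Het mice. Lists that turned direction under it, none of them called any longer, were endothelial markers for genotype in vehicle females (adjusted p = 0.704), microglia and mural markers for fluoxetine in Het females (adjusted p = 0.517 and 0.602), and astrocyte, microglia and endothelial markers for lithium in Het females (adjusted p = 0.832, 0.363 and 0.600). With 4 scores the counts were 12 and 1 for genotype in vehicle males and females, 1723 and 1186 for fluoxetine in Het males and females, 191, 317, 164 and 204 for lithium in WT males, WT females, Het males and Het females, 79 and 2 for genotype in fluoxetine males and females, 2 for genotype in lithium males, 3739 for the Het fluoxetine average, 1646 and 679 for the lithium averages and 1 for the sex by fluoxetine interaction in Het mice. Turned lists were mural markers for fluoxetine in Het females (adjusted p = 0.978), astrocyte and endothelial markers for lithium in Het males (adjusted p = 0.951 and 0.897) and microglia and endothelial markers for lithium in Het females (adjusted p = 0.988 and 0.976). For the genes fluoxetine called in Het males, the median size of the change was 0.30 in the main test and 0.22 with 4 scores, and for Het females 0.31 and 0.23. Over the turned lists of this paragraph and the next, the adjusted p over all alternatives, single libraries left out included, ran from 2.522e-06 to 0.988.

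Without the 16 libraries, which leaves fewer samples, the counts were 1 and 28 for genotype in vehicle males and females, 87 and 293 for fluoxetine in WT females and Het males, 2, 4 and 942 for lithium in WT females, Het males and Het females, 4 for genotype in fluoxetine females, 19 for the genotype average, 770 and 3152 for the WT and Het fluoxetine averages, 179 and 577 for the lithium averages, and 1, 2, 39 and 1 for the interactions of genotype and fluoxetine in males, in females, of sex and fluoxetine in Het mice and of genotype and lithium in males. Choroid plexus markers for lithium in WT males (adjusted p = 0.985) and autism risk genes for lithium in WT females (adjusted p = 0.518) turned direction. Correlations became −0.648 for genotype and lithium effects in females, 0.166 for fluoxetine between sexes in WT and 0.108 for lithium between sexes in Het mice.

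Voom called 1 and 2 genes for genotype in vehicle males and females, 9 for lithium in WT females and 4 for genotype in fluoxetine females, and edgeR 1 for the sex by fluoxetine interaction in Het mice. DESeq2 called 9 and 8 for genotype in vehicle males and females, 27, 96, 806 and 289 for lithium in WT males, WT females, Het males and Het females, 460 and 34 for genotype in fluoxetine males and females, 4 for genotype in lithium males, 17 for the genotype average, and 413, 18, 4, 1, 1 and 1 for the interactions of genotype and fluoxetine in males and females, sex and fluoxetine in WT, genotype and lithium in males and females, and sex and genotype. Of 310 list tests 0 were called with an estimated correlation and 16 with fry. Vehicle libraries split between comparisons gave −0.18, −0.135, −0.087 and −0.018 for genotype and drug effects and 0.069, 0.095, 0.227 and 0.142 for fluoxetine and lithium effects, as sharing was removed. Rank correlations were 0.465 for fluoxetine between sexes in WT, 0.365 for lithium between genotypes in males and 0.35 for lithium between sexes in WT mice.

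Leaving out each library in turn gave 0 (without Het vehicle male replicate 1) to 7 genes (without its replicate 5) for genotype in vehicle males, and 0 (Het vehicle female replicate 4) to 8 (replicate 2) in females. Fluoxetine ranged from 151 (WT fluoxetine male replicate 2) to 230 in WT males, 177 (WT vehicle female replicate 5) to 494 in WT females, 2323 (Het fluoxetine male replicate 3) to 4418 in Het males and 1298 (Het vehicle female replicate 3) to 3277 in Het females. Lithium ranged from 0 (WT lithium male replicate 3) to 4 in WT males, where all 10 moved the count over 1.5 times, 0 (WT lithium female replicate 5) to 28 in WT females, 71 (Het vehicle male replicate 1) to 1103 (replicate 3) in Het males and 7 (Het vehicle female replicate 3) to 254 (replicate 2) in Het females. Genotype ranged from 52 (WT fluoxetine male replicate 1) to 809 (Het fluoxetine male replicate 1) in fluoxetine males, 2 (WT fluoxetine female replicate 5) to 26 (Het fluoxetine female replicate 4) in fluoxetine females, 1 to 2 (WT lithium male replicate 5) in lithium males and 3 to 4 in lithium females. The averages ranged from 5 (WT vehicle male replicate 3) to 12 for genotype, 1013 to 1596 and 5139 to 6282 for fluoxetine in WT and Het mice, and 249 (WT lithium male replicate 4) to 600 and 967 (Het vehicle male replicate 1) to 2401 for lithium. Interactions ranged from 9 (Het vehicle male replicate 1) to 695 (WT fluoxetine male replicate 5) for genotype and fluoxetine in males, 0 to 1 in females, 1 to 92 (Het fluoxetine male replicate 5) for sex and fluoxetine in Het mice and 0 to 0 for the others, and male against female from 9 to 13. Called list tests ranged from 89 to 106. Without Het vehicle male replicate 3 the ribosomal list turned direction for genotype in vehicle males (camera, adjusted p = 0.888; 9.955e-08 without replicate 1). Correlations of genotype and drug effects ranged from −0.651 to −0.528 and −0.629 to −0.461 for fluoxetine in males and females and −0.637 to −0.488 and −0.545 to −0.363 for lithium. For fluoxetine they ranged from 0.164 to 0.315 and 0.05 to 0.188 between genotypes and 0.248 to 0.336 and 0.237 to 0.419 between sexes, and for lithium from 0.137 to 0.257, 0.222 to 0.357, 0.162 to 0.232 and 0.194 to 0.329. Between the drugs they ranged from 0.46 to 0.562, 0.408 to 0.535, 0.515 to 0.668 and 0.407 to 0.589.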

Other observations

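Tests chosen after seeing the data were the score permutations and the comparison of genotypes over 6 combinations of drug and sex. Over all 6, Het mice had less Usp11 (−0.17 ± 0.02, adjusted p = 7.21e-08), a deubiquitinase, less of the noncoding RNA Rian (−0.15 ± 0.02, adjusted p = 4.03e-06) and less Cyp11a1 (−0.37 ± 0.06), the first enzyme of steroid synthesis. They had more Rad51d (0.18 ± 0.02, adjusted p = 3.29e-06), a DNA repair gene, and more of the replication clamp gene Pcna (0.14 ± 0.02). In all 274 genes were called (111 higher, 163 lower; 2632 at an unadjusted p under 0.05). Glud1 stood at −0.42 ± 0.03 and Entpd4 at −0.39 ± 0.03, and their chromosome 14 neighbors Sncg, a synuclein gene (34370274 to 34374789), at −0.89 ± 0.11, Mmrn2 at −0.37 ± 0.06 and Gm16867 at −1.83 ± 0.18. Sncg and Gm16867 were outside the naming rule and were chosen after their values were seen, and Sncg had few counts, 17.7 in Het and 32.5 in WT mice.

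Gene list scores were compared over all 4 combinations of genotype and sex, 20 treated against 20 vehicle libraries, by two-sided permutation within combinations with adjustment over 93 tests. With fluoxetine, immediate early genes (−0.56), cholesterol synthesis genes (−0.26) and glucocorticoid-responsive genes (0.45) changed with an adjusted permutation p = 0.000233, from the smallest p that 100000 permutations can give (1e-05). Wnt targets were lower by this test (−0.16, adjusted permutation p = 0.00171), as were oligodendrocyte precursor markers (−0.10, adjusted permutation p = 0.0171). Glucocorticoid scores with fluoxetine were uneven. WT female replicates 4 and 5 and male replicate 5 stood at 0.333 to 0.432. Het female replicates 2 to 5 and male replicates 3 to 5 stood at 0.355 to 0.633, and the other fluoxetine libraries at −0.158 to 0.135. Cholesterol scores were −0.384 to −0.216 in the libraries with high glucocorticoid scores and −0.12 to 0.011 in the other fluoxetine libraries. The source of this split was not tested. With lithium, oxidative phosphorylation (0.15), erythrocyte (0.73), heat shock (0.13) and glucocorticoid-responsive genes (0.27) were higher (adjusted permutation p = 0.000233, 0.000558, 0.00531 and 0.00791). Postsynaptic density genes (−0.04) and Wnt targets (−0.13) were lower (adjusted permutation p = 0.0356 and 0.0183). No tissue score entered these permutations, so they do not exclude neighboring tissue, for either drug. Each named list moved the same way in all 4 combinations. Glucocorticoid scores with lithium were also uneven. They were 0.531 and 0.467 in Het male replicates 4 and 5, 0.49 in Het female replicate 5 and 0.453 in WT male replicate 5. The other lithium libraries stood at −0.289 to 0.18. The Het minus WT difference of the fluoxetine effect was 0.336 ± 0.133 (SE) for the glucocorticoid score, 0.136 ± 0.123 for immediate early genes and −0.114 ± 0.071 for cholesterol synthesis. High glucocorticoid scores were found in more Het than WT fluoxetine libraries, and the glucocorticoid difference was not separated from that uneven spread.

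Some genes were called in 5 of the 10 main comparisons. Lrfn2, a synaptic adhesion gene, had positive changes with both drugs in all groups and was not called with fluoxetine in WT mice, at 0.32, 0.33, 0.51 and 0.57 with fluoxetine and 0.49, 0.28, 0.41 and 0.41 with lithium in WT males, WT females, Het males and Het females. The cyclin gene Ccnd2 stood at −0.37, −0.32, −0.27 and −0.33 with fluoxetine and at 0.11, 0.15, 0.29 and 0.09 with lithium. Rara, a retinoic acid receptor gene, stood at −0.68, −0.51, −0.50 and −0.34 with fluoxetine and at 0.33, 0.26, 0.38 and 0.32 with lithium. Pam16 was called in 3 comparisons that all rest on WT vehicle females, where it stood at 75.9 ± 7.85 counts (SD, n = 5).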
